A study of Drosophila melanogaster with 3 samples.

How the data were processed

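The series holds 3 two-colour cDNA arrays of Kc167, an established embryonic cell line of Drosophila melanogaster. Per the labels, both channels of each array carried RNA of the same untreated cells, so each is a homotypic, or self-self, hybridisation, in which the signal of the 2 channels should be equal for every gene. The arrays differ in the amount of total RNA put into each labelling reaction, which was 20, 40 or 80 µg, with 1 array per amount. Per the labels, the cells were grown at 22 °C, RNA was extracted with Trizol, cDNA was labelled directly with Cy3 or Cy5, and hybridisation lasted 15.75 hours.

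Per the labels, the slides were read with a ScanArray scanner and quantified in QuantArray with its adaptive algorithm and no background subtraction, and the authors derived the deposited value from normalized data. The normalization method, the reason for empty cells, the log base and the dye in the numerator are not given in the sources used here. The deposited values are signed, centred near 0 and were read as log2 ratios. The range argues against base 10, but a natural log cannot be told from base 2 in these files, and fold thresholds would then apply to other values. The sign is that of the deposited value, and no direction between Cy3 and Cy5 is given. Intensities were not analysed here, so dim and bright spots could not be told apart, and the number of arrays limits the precision.

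The table has 16896 spots. A platform annotation gave exactly 1 gene symbol to 5666 spots, several to 152 and none listed to 11078. The 2377 genes named this way were all found by gene identifier in a gene table of Drosophila melanogaster. Each of the 2833 odd-numbered spots with 1 gene was followed by a spot of the same gene, so probes were printed as side-by-side duplicates. Spots of 1 gene were averaged on each array, spots without a single gene name stayed as they were, and only features with a value on all 3 arrays were used. This left 11845 features, of which 2314 were genes and 9531 single spots. Unnamed spots were not paired, so duplicates of a probe can count there as separate features. A single spot carries more error than a mean over spots, and cDNA probes can also bind transcripts of close paralogs, so members of gene families are less certain. The deposited order of spots repeats with a period of 24, and the table was divided into 32 segments of 528 consecutive spots. These segments were inferred from the values and are taken to follow the printing blocks, which is not stated. No genome build is named for the probes, so no coordinates are given.

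The spread of the log2 ratio, the share of features beyond 1.5-fold and the duplicate-spot error were computed for each array. Their intervals came from 1000 bootstrap resamples of features or of spot pairs or, for shares, were Wilson 95% intervals. They cover the choice of features or counting error only. They also take features or pairs as independent, although neighbouring spots correlated, so they may be too narrow. With 1 array per amount no p-value compares the arrays. All 3 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), once for a mean that departs from 0 and once for a slope on the log2 amount of RNA, with Benjamini-Hochberg adjustment and a threshold of 0.05. The slope leaves 1 residual degree of freedom per feature before moderation. Every ± value is limma's SE after moderation, which draws the spread of each feature toward that of all features. Gene lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 against the other named genes, and each list's median was ranked among 10000 random lists of named genes of the same size. Matching these lists on expression was not possible without intensities. Of 17 lists fixed, 10 had enough genes. The labels do not say that the RNA came from separate cultures, so p-values measure the spread between arrays, which may be technical.

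The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the genes with the largest mean of 1 sign on all 3 arrays (up to 10 per sign that passed the test, or 5 per sign where fewer did), the 5 largest ordered rises and falls with RNA amount, the 2 members of each tested list with the largest mean, and RpL32, the 1 measured gene of 4 commonly used reference genes. On simulated data made by shuffling each array's values over the 11845 features and changing 200 genes, the fit for a mean recovered 65% of genes changed by 1 on the log2 scale, 97.5% of those changed by 2 and none (0%) of those changed by 0.5. The slope fit recovered 97.5% at 2 per doubling and none (0%) at 1. Camera recovered a list shifted by 0.2 in 78% of 50 simulations. In the fits per gene, shuffling gave the 200 genes the spread of all features, which was wider than that of named genes. In each simulation it also removed effects of position and correlation between genes. The shares are therefore not detection limits for the real data. Alternatives tried were median centring, equal scaling of the arrays, single spots, genes with at least 2 spots on every array, a robust fit, other spread measures and thresholds, and leaving out each array in turn; added after seeing the data were named genes only, natural logs, all features as the background of the gene lists, the median spread over segments, and leaving out the first 4 segments, which hold the first 2112 spots. A scan for wide windows of 4 consecutive segments, set after the first 4 were seen to be wide, gave a mean SD above that of 1000 shuffles of the spots on all 3 arrays (0.709, 0.387 and 0.447, against at most 0.417, 0.366 and 0.370) and was used for no explanation, nor was a comparison without each array's own widest segments, which selects on the spread itself.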

Results

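Drosophila Kc167 RNA was hybridised against itself on 3 two-colour arrays, with 20, 40 or 80 µg of RNA in each labelling reaction and 1 array per amount. Values were present for 15853 spots at 20 µg, 16313 at 40 µg and 15623 at 80 µg, of 16896 spots on each array. The analysis covered 11845 features on all 3 arrays, of which 2314 were named genes. The design asks how far ratios depart from equality when the RNA is identical, and whether the amount of RNA changes that.

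No gene departed from equal signal on all 3 arrays by the test used. The adjusted p from limma with Benjamini-Hochberg adjustment was at least 0.749 for each of the 11845 features (0 calls), and 670 features, or 5.66%, had an unadjusted p below 0.05, where chance gives 592. Among the named genes 91 of 2314 did so, where chance gives 116, and of the 91, 42 had a positive and 49 a negative mean. With limma fitted to the named genes only, 146 of 2314, or 6.31%, did so, again with 0 calls. Whether the count of named genes lay below or above chance thus depended on which features shared the moderation. The 5 largest positive means of constant sign belonged to PrBP, a prenyl-binding protein (0.81 ± 0.22, SE, n = 3 arrays), CG12860 (0.73 ± 0.27), Obp19b, an odorant-binding protein (0.69 ± 0.22), Nop17l (0.63 ± 0.31) and wit, a type II receptor of the BMP pathway (0.62 ± 0.08). The largest negative means belonged to mlt (-0.92 ± 0.36), CG12713 (-0.84 ± 0.26), CG17027 (-0.76 ± 0.35), CG15034 (-0.74 ± 0.16) and CG7889 (-0.70 ± 0.39). All of these had an adjusted p of 0.749 with limma. Their SEs are moderated, and the plain SD over the 3 arrays was 0.548 for PrBP, 1.02 for CG7889 and 0.011 for wit.

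The size of most of these means came from 1 or 2 arrays. Nop17l was at 1.54 on the 20 µg array and at 0.18 and 0.16 on the 40 and 80 µg arrays, and CG7889 was at -1.88, -0.08 and -0.15. The gene mlt was at -1.97 on the 80 µg array and at -0.65 and -0.13 at 20 and 40 µg. CG15034 was less uneven, at -0.81, -0.34 and -1.07. The gene wit (Entrez Gene identifier 44096) was the most even of these genes, with log2 ratios of 0.61, 0.62 and 0.63 and an unadjusted limma p of 0.000813. It was the only named gene beyond 1.5-fold with 1 sign on all 3 arrays. A further 12 single unnamed spots met that criterion, all of them negative. In no case did the adjacent spot of the odd-even pair meet it too, though that spot may lack a value. Of these 13 features, 11 lay in the first 2112 spots of the deposited order, where 1.88 would be expected if the arrays were independent within that stretch. The other 2 lay in the remainder, where 0.254 would be expected; they were spots 7482 and 11547, with means of -0.74 and -0.82, and are named after their values were seen. Of the 10 genes named above, 8 had spots in the same stretch, against 14.8% of all named genes.

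No gene changed with the amount of RNA by the test used. The adjusted p of the limma slope was at least 0.825 (0 calls), and 700 features, or 5.91%, had an unadjusted p below 0.05. The largest ordered rises from 20 to 80 µg were those of CG5850 (-0.93, 0.46 and 0.81), hob (-1.55, -0.17 and 0.12), Adsl, the adenylosuccinate lyase of purine synthesis (-1.44, -0.77 and 0.15), CG5065 (-1.55, -0.11 and 0.01) and rad50, a component of a DNA break repair complex (-0.00048, 0.14 and 1.55). The largest ordered falls were those of CG12069 (1.61, 0.28 and -0.66), CG6441 (0.39, 0.27 and -1.64), CG5770 (0.12, -0.17 and -1.63), Gtpx (1.21, -0.07 and -0.40) and CG17564 (1.22, -0.09 and -0.39). CG12069 had the steepest slope of the 10, -1.13 ± 0.13 per doubling of RNA (SE, 3 arrays; adjusted p of 0.825 with limma). Both spots of each of these 10 genes lay in the first 2112 spots. Among named genes, 333 rose in order and 462 fell in order, or 14.4% and 20.0%, where 3 values without order give 16.7% of each. The arrays were not centred for these counts, and their medians over all features also fell in order (0.016, 0.0094 and -0.0012). An excess of falls therefore need not come from single genes.

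**Figure D1:**
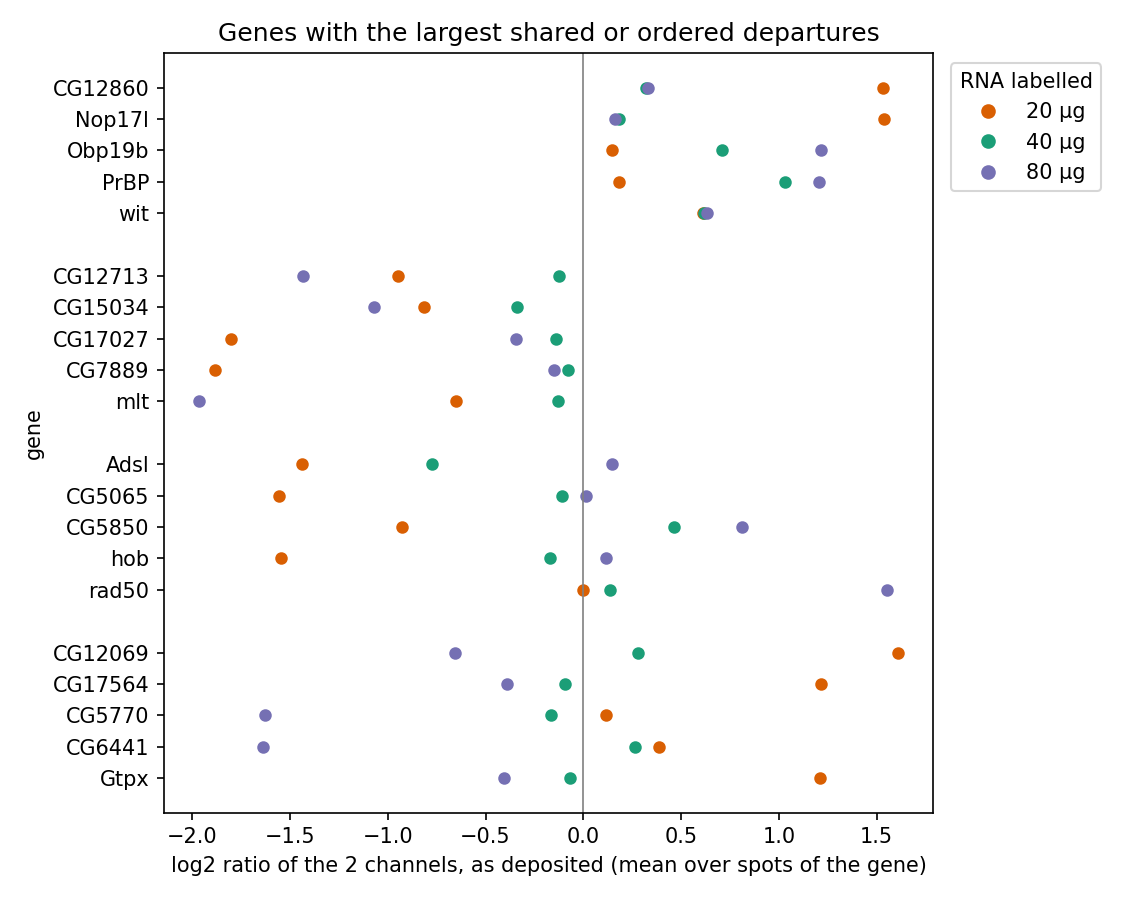
Mean log2 ratio over the spots of each gene (x axis, as deposited) for the genes with the largest means of 1 sign and the largest ordered rises and falls, with 1 point per array coloured by RNA amount. The 3 points of wit lie together at 0.61 to 0.63, whereas most other genes have a single array far from 0.

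Of the 10 gene lists tested, 0 departed from the other named genes by camera at an adjusted p below 0.05, and 1 did so at an unadjusted p. No member of any list passed the test per gene, neither over all features nor adjusted over the list alone (0 calls; the lowest adjusted p over a list alone was 0.0783, in the neuronal list). The list with the lowest p was that of ecdysone response genes, whose 6 members had negative means in 6 of 6 cases, 2 of them with 1 sign on all 3 arrays, and a median of -0.16 (camera p of 0.0168, or 0.0878 without the 20 µg array; adjusted p = 0.168, and adjusted p = 0.983 with an estimated correlation). Its list median was -0.26, -0.17 and -0.11 at 20, 40 and 80 µg, at percentiles 0.39, 2.39 and 9.98 of random lists. The 2 of constant sign were Eip63E, a cyclin-dependent kinase gene, with a mean of -0.23 ± 0.09 (SE, n = 3 arrays), and ImpL2, a secreted binder of insulin-like peptides, with -0.19 ± 0.09.

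Lists of general cell functions had members of both signs (means are ± moderated SE over 3 arrays here and in the next paragraph). Without intensities, it could not be told which members were expressed in these cells. In the proteasome list, 9 of 14 members had positive and 5 negative means, with the largest at Prosbeta5R1 (0.26 ± 0.12) and Rpn6, of the regulatory particle (-0.17 ± 0.15). The sign of the Rpn6 mean rested on the 20 µg array, and was 0.022 without it. The chaperone list had 7 positive and 6 negative means of 13, among them DnaJ-1, an Hsp40 chaperone with 16 spots (-0.19 ± 0.08), and the chaperonin subunit CCT5 (0.18 ± 0.09, and 0.09 without the first 2112 spots). Of the 10 translation factors, 4 were positive and 6 negative, with eIF3f2 at -0.23 ± 0.09 and eIF6 at -0.20 ± 0.09. The 8 respiratory chain members split into 4 and 4, with the complex I subunit ND-B8 at -0.23 ± 0.09 and ATPsynGL at -0.22 ± 0.17. The ATPsynGL mean rested on the 40 µg array, and was 0.0041 without it. The cytosolic ribosomal proteins had 2 positive and 3 negative means. RpL32, often used as a reference gene, had -0.20 ± 0.09 over 18 spots and -0.02 without the 10 that lay among the first 2112, and RpS10a had 0.09 ± 0.10 (0.0045 without the 40 µg array). In the cytoskeleton list 5 of 10 means were positive, with betaTub65B, a tubulin with both spots among the first 2112, at 0.28 ± 0.13 (0.125 without the 20 µg array) and alphaTub85E at -0.19 ± 0.10.

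Lists of cell-type genes also did not pass. The haemocyte list, of the blood cell type that Kc167 cells resemble, had 2 positive and 3 negative means, with the phagocytic receptor NimC1 at -0.16 ± 0.08 and SPARC, a matrix glycoprotein, at -0.09 ± 0.09 (-0.045 without the 20 µg array). Muscle genes had 3 positive and 3 negative means, with Tm2, a tropomyosin with both spots among the first 2112, at 0.20 ± 0.14 (0.034 without the 80 µg array) and Prm, the paramyosin gene, at 0.14 ± 0.09. Neuronal genes had 3 positive and 2 negative means, with fne, of the ELAV family, at -0.54 ± 0.15 (-0.18 without its 2 spots among the first 2112) and futsch, a microtubule-associated protein, at 0.24 ± 0.11. The lowest camera p of the other 9 lists, ecdysone apart, was 0.245, for translation factors. It was 0.0386 without the 40 µg array (adjusted p = 0.193), and that of the cytosolic ribosomal proteins fell from 0.566 to 0.0453 with each spot on its own (adjusted p = 0.226). The median and the mean of the means differed in sign for the respiratory chain, chaperone and neuronal lists. Their medians were positive and the direction given by camera was up. With each spot on its own, camera gave the direction down for each of these lists.

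**Figure D2:**
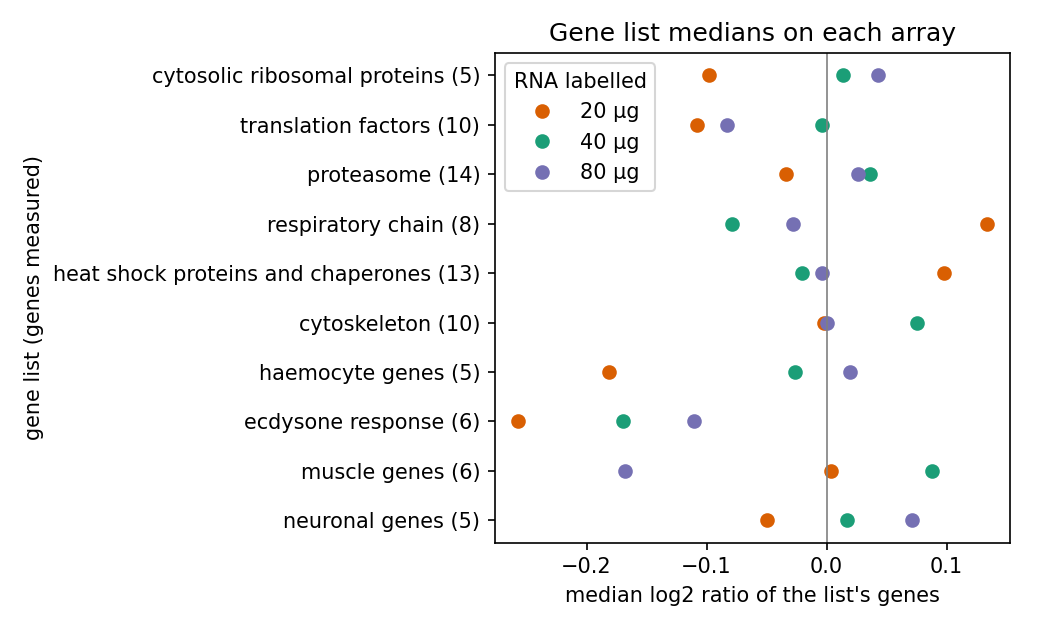
Median log2 ratio of the measured genes of each list (x axis) on each array, coloured by RNA amount, with the number of genes in brackets. The ecdysone list is the only one whose 3 medians, from -0.26 to -0.11, all lie below -0.1.

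The spread of the log ratio over features was widest at 20 µg. Its SD was 0.354 (bootstrap 95% interval 0.342 to 0.365) at 20 µg, 0.304 (0.295 to 0.314) at 40 µg and 0.305 (0.296 to 0.315) at 80 µg. As scaled median absolute deviation the spread was 0.238, 0.210 and 0.191. Without the first 2112 spots the order of the SDs changed, with SDs of 0.266 at 20 µg, 0.297 at 40 µg and 0.277 at 80 µg. Those spots had an SD of 0.712 at 20 µg, 0.361 at 40 µg and 0.467 at 80 µg, against 0.284, 0.317 and 0.300 in the other spots. With no replicate array, none of these differences was tested.

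The share of features beyond 1.5-fold was 6.71% at 20 µg (795 of 11845; Wilson 95% interval 6.27 to 7.18%), 5.16% at 40 µg (4.77 to 5.57%) and 5.80% at 80 µg (5.39 to 6.24%). Without the first 2112 spots it was 2.69%, 4.76% and 4.85%. Negative values predominated, with 464 negative and 331 positive at 20 µg, 444 and 167 at 40 µg, and 582 and 105 at 80 µg. Read as natural logs, the same values would place 14.3%, 11.3% and 11.5% of features beyond 1.5-fold. The array medians were 0.016, 0.0094 and -0.0012.

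**Figure D3:**
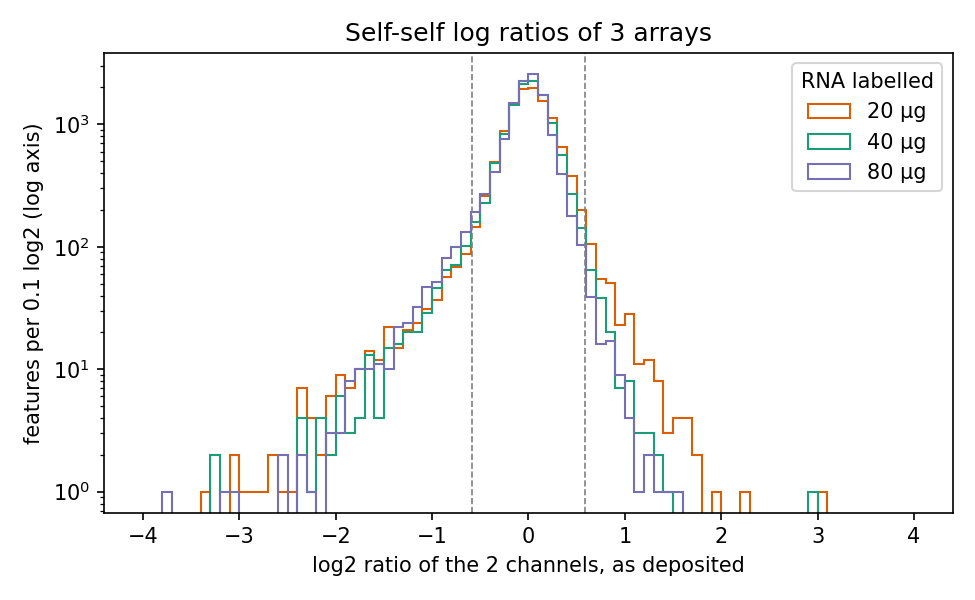
Number of features (log axis) per 0.1 of log2 ratio on each array, with dashed lines at 1.5-fold. The negative tail is longer than the positive tail on each array, and the positive tail reaches furthest on the 20 µg array, where 331 features lie beyond 1.5-fold against 167 and 105.

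**Figure D4:**
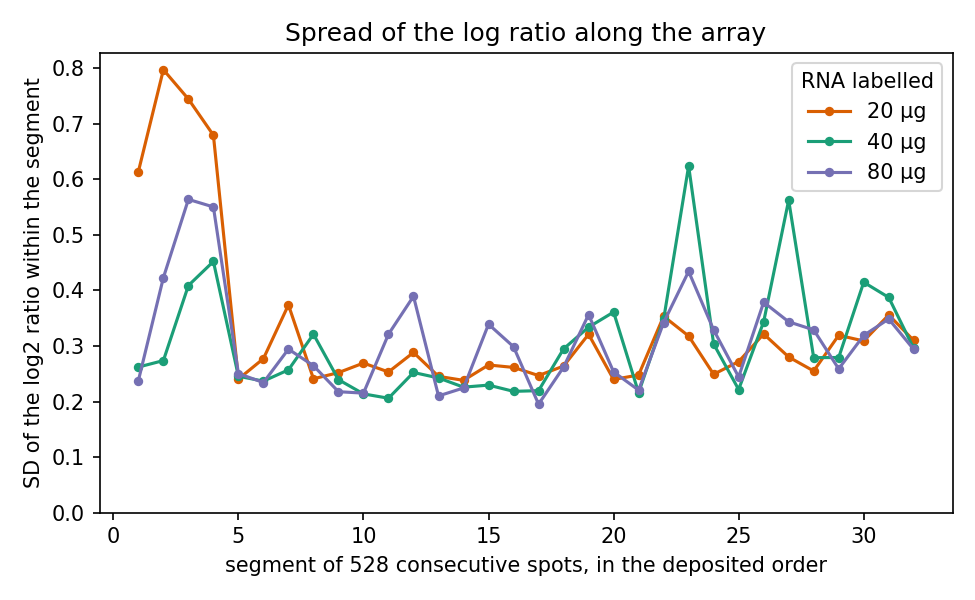
SD of the log2 ratio within each of 32 segments of 528 consecutive spots, in the deposited order, for each array. The first 4 segments of the 20 µg array reach 0.798, and the 40 µg array has its widest segment, 0.624, elsewhere.

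Duplicate spots of a gene on 1 array differed by an SD per spot of 0.296 at 20 µg (0.280 to 0.315, 2572 pairs), 0.260 at 40 µg (0.249 to 0.271, 2713 pairs) and 0.248 at 80 µg (0.235 to 0.260, 2570 pairs). Their correlation across pairs was 0.297, 0.351 and 0.369 as Pearson's r, and 0.166, 0.255 and 0.310 as Spearman's rho.

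Departures recurred only weakly between arrays. Across features, which are not independent replicates, Pearson's r was 0.059 between 20 and 40 µg (Spearman's rho 0.068), 0.092 between 20 and 80 µg (0.092) and 0.123 between 40 and 80 µg (0.123). Without the first 2112 spots r was 0.020, 0.051 and 0.097. The sign was the same for 52.9%, 53.5% and 55.1% of features. Of named genes, 12 lay beyond 1.5-fold on both the 20 and 40 µg arrays, where independent lists share 3.86, and 7 of the 12 had the same sign. The pair of 20 and 80 µg shared 10 genes (4.04 expected, 8 of the same sign), and that of 40 and 80 µg shared 8 (3.27 expected, 7 of the same sign). These expected counts treat all named genes as equally likely to pass. The first 2112 spots had a wider SD than the other spots on each array, which alone can raise the shared counts. The excess therefore does not show that departures of single genes recurred.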

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

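Empty cells, which no comparison used, coincided between arrays: 45 spots were empty on all 3 arrays, where 2.71 would be expected if cells were empty independently. When a spot was empty, its duplicate was empty on another array in 21.3% of cases and the neighbouring spot of another probe in 11.8%, against 5.72% of all cells.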

How the results depend on the processing

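The counts of features that departed from 0, of features with a slope and of gene lists past the threshold were 0 under each alternative run; leaving out each array in turn gave 0 to 0 for the first and the last of these, and it leaves no residual degrees of freedom for the slope. No paired analysis was possible because there was 1 array per RNA amount. For a departure from 0, between 4.25% and 6.36% of features had an unadjusted p below 0.05 over these settings, and for a slope between 4.85% and 6.65%. Only 2 single genes changed sign, both when 1 array was left out. Rpn6 ranged from -0.27 to 0.022 and ATPsynGL from -0.35 to 0.0041. The other 221 values of single named genes kept their sign and stayed short of the threshold. Apart from Rpn6, ATPsynGL, Prosbeta5R1 and RpS10a, each mean came from values of 1 sign on all 3 arrays. Leaving out an array could not change the sign of such a mean. The values that follow are for 20, 40 and 80 µg. The SD was 0.365, 0.317 and 0.315 over single spots; 0.273, 0.235 and 0.231 with at least 2 spots on every array; 0.279, 0.246 and 0.251 for named genes; 0.305, 0.267 and 0.269 without the 1% most extreme features; 0.238, 0.210 and 0.191 as scaled median absolute deviation; 0.275, 0.276 and 0.297 as the median over segments; and 0.266, 0.297 and 0.277 without the first 4 segments. The share beyond 1.5-fold was 7.34% and 5.66% over single spots at 20 and 40 µg; 4.37%, 3.49% and 2.86% with at least 2 spots; 4.54%, 3.67% and 3.85% for named genes; 2.69%, 4.76% and 4.85% without the first 4 segments; and 14.3%, 11.3% and 11.5% for natural logs. The share beyond 2-fold was 2.27%, 1.36% and 1.67%. The duplicate SD was 0.236, 0.198 and 0.166 as median absolute deviation, and 0.267 at 20 µg without the first 4 segments. Without those segments r fell to 0.020 between 20 and 40 µg and to 0.051 between 20 and 80 µg. The 20 µg array was thus the widest by most measures but not without the first 4 segments or as a median over segments. Median centring moved none of the spreads, shares and correlations beyond its interval.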

Other observations

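The tests in this part were chosen after the spread of the segments had been seen, except the count of segments by median absolute deviation. Small lists were not tested but had measured members. Of the mitochondrial ribosomal proteins, mRpL54 had a mean log2 ratio of -0.68 ± 0.24 (SE, n = 3 arrays), from -1.30 at 20 µg through -0.61 to -0.12 at 80 µg, whereas mRpL13 was at -0.16 and mRpL16 at -0.06. Of the immune genes, Tep4, a thioester-containing protein, was at -0.33 ± 0.09 with the same sign on all 3 arrays, and Dif, a transcription factor of the Toll pathway, was at -0.22 ± 0.16. The fat body list had apolpp, the lipophorin gene, at -0.14, Obp99a at -0.04, Obp99c at -0.01 and Obp99d at 0.05, and the germline gene exu was at -0.03. The glycolysis, histone and cell cycle lists had no measured member (0 each).

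Genes printed many times show how far spots of 1 gene differ, which can include position on the slide besides the error of single spots. RpL32, with 18 spots, had an SD over spots of 0.488 at 20 µg, 0.566 at 40 µg and 0.537 at 80 µg. Its spots ranged from -1.18 to 0.749 at 20 µg although all were matched to the same gene. Of these spots, 10 lay among the first 2112. DnaJ-1, with 16 spots and none (0) among the first 2112, had an SD over spots of 0.262, 0.295 and 0.388 at 20, 40 and 80 µg. CG9016, with 38 spots and 4 of them among the first 2112, had 0.265, 0.271 and 0.495. Its mean over spots was 0.09, -0.06 and -0.20.

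The 20 µg array had the widest SD. Over the 32 segments, the median ratio of the 20 µg SD to the mean of the other 2 arrays was 1.02 (95% interval over segments 0.939 to 1.12), and the ratio over all spots was 1.13 (0.936 to 1.32). The difference of 0.107 (-0.053 to 0.274, with segments resampled for both) was too uncertain to tell whether the excess was spread over the slide. With 1 array per amount, even a precise difference could not separate the amount of RNA from the individual array. Whether the amount was the source therefore stays open. A region of the slide also stays open, since the wide first 2112 spots were found in these same values.

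The central spread behaved otherwise. The median absolute deviation fell from 0.238 at 20 µg to 0.210 at 40 µg and 0.191 at 80 µg. It was larger at 20 than at 80 µg in 25 of the 32 segments, with a median ratio of 1.27 (1.11 to 1.41), which argues against a region of the slide. The order of 20 above 40 above 80 µg held in 13 of the 32 segments, where 3 values without order give 16.7% of segments. The median absolute deviation was larger at 20 than at 40 µg in 25 segments, and larger at 40 than at 80 µg in 20. With 1 array per amount, the amount and the individual array cannot be told apart.

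The 2 spots of a probe may agree in part because they lie side by side. Neighbouring spots of different probes correlated (Pearson's r) at 0.209, 0.278 and 0.288 on the 20, 40 and 80 µg arrays, at least 0.705 of the correlation of duplicates on each, and spots one row of 24 apart at 0.254, 0.302 and 0.282. By Spearman's rho the neighbours were at 0.113, 0.208 and 0.263, at least 0.680 of the duplicates. Duplicates were pairs of named genes (2572, 2713 and 2570), whereas neighbours came from all spots, named or not (6860, 7239 and 6715 pairs). For unnamed spots, a different probe was inferred from the odd-even layout. These shares therefore compare unlike sets of spots and cannot show how much of the agreement comes from position. The covariance of duplicates in excess of neighbours was 0.243 times as large between arrays as within them, with an interval from -0.453 to 0.618. A ratio of 1 would be found if all of the rest were a dye effect of the gene that recurs on every array. The interval lies below 1, which argues against that for the whole of it. Whether a part of the rest is such an effect stays open, as the interval was too wide to decide.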
